A study of Rattus norvegicus with 9 samples.

How the data were processed

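Messenger RNA was measured in brain cortex of rats with a 1-colour Illumina bead array for rat, on 9 arrays. According to the labels, 3 arrays hold cortex of rats kept at a simulated altitude of 7 km, 3 hold cortex of rats at 3 km and 3 hold cortex at sea level. No label says that the replicates of a group are separate animals, so every p-value measures only the spread between samples. Per the labels, RNA was extracted with Trizol, cleaned up with a column kit and DNase I, and turned into biotin-labelled cRNA with a MessageAmp kit. The scanner, its software, the slide of each array and the length of the exposure are not given in the sources used here.

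The deposited non-normalized table gives 1 signal (intensity) and 1 detection p-value for each of 22523 probes on each array. All signals were positive and the medians differed between arrays, so no background had been subtracted and no normalization between arrays had been done. The deposited detection p-value falls as the signal rises on every array and moves in steps of 1 over 825, which is the form of a rank among negative control beads. The authors also deposited a value table of 21675 of these probes, in intensity units on a linear scale. Its columns have means of 208 to 209 and medians from -23.0 to 19.5, and 29.3 to 58.8% of a column's values lie below 0. That table is background-subtracted and scaled to nearly equal means, by a method that is not stated, and its columns had Spearman correlations of at least 0.990 with the signals of the same arrays. It served as an alternative. The other 848 probes are missing from it for a reason that is not stated.

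Signals were corrected and normalized with the neqc function of limma 3.58.1 in R 4.3.3. The negative control distribution was inferred from the detection p-values, an offset of 16 was added, arrays were quantile normalized, and values were taken to log2. The offset pulls the log2 differences of dim probes towards 0. Probes with a detection p-value below 0.05 on at least 3 arrays were tested, which left 6656 probes with all 9 arrays and 6499 without sea level replicate 3. Of all probes, 13353 carry 1 gene symbol in the platform annotation, 0 carry several and 9170 carry none; 13313 of the named ones matched the current RefSeq table. Unnamed probes were tested and counted but not named.

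A limma model with a mean per group was fitted over all arrays. Its 3 contrasts were 7 km against sea level, 3 km against sea level and 7 km against 3 km, with eBayes without trend and Benjamini-Hochberg adjustment over the probes tested, at an adjusted p of 0.05. All adjusted p-values in the text are from limma. Values after ± are standard errors from that model, with 3 arrays per group unless another number is given. The number of arrays limits the precision of every value. Where a probe was not above background on any array of a group, its fold is given as a bound: the mean of the brighter group against the higher of the lowest detected level and the probe's own level in the dimmer group.

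Gene lists were tested with camera, a test in limma of whether the genes of a list move against the other genes, with a preset correlation between genes of 0.01 and 1 probe per gene, the brightest. Of the 40 lists, 36 had at least 5 tested members. The process lists are HIF targets, glycolysis, oxidative phosphorylation, TCA cycle, antioxidant and oxidative stress, immediate early genes, heat shock and chaperones, unfolded protein response, glucocorticoid-responsive genes, inflammation and cytokines, and interferon response and antigen presentation. Further process lists are apoptosis, coagulation with fibrinolysis and matrix proteases, angiogenesis, glutamate receptors and synapse, synaptic vesicle release, ion channels and pumps, circadian clock, cholesterol synthesis, ribosomal proteins, proteasome, cell cycle, autophagy and lysosome, and iron handling. The lists of cell and region markers are excitatory cortical neurons, interneurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and macrophages, endothelium, pericytes and vascular smooth muscle, meninges and fibroblasts, and choroid plexus and ependyma. The others are red cells, leukocytes, hippocampus, striatum, thalamus, and hypothalamus and pituitary. Camera was also run with the correlation estimated for each list, and fry, another set test of limma, was run beside it. Members were further adjusted over the list alone.

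The named genes were chosen by a rule. For each contrast it takes the 10 named genes with the largest rise and the 10 with the largest fall among those that passed and whose arrays did not overlap between the groups. If fewer than 5 passed in a direction, it fills up to 5 by the smallest p, given as values that did not pass. It adds up to 4 members per list with the smallest p in each contrast, and always Tfpi2, Hif1a, Epas1, Vegfa, Slc2a1 and Hmox1. The lists, this rule, the model, the contrasts and most alternatives were fixed before the data were examined. Leaving out each array in turn was among them. Giving many values without sea level replicate 3 as well as with all 9 arrays, and 3 alternatives that leave it out together with another change, were chosen after seeing the data.

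The alternatives were no background correction, an offset of 50, scaling to equal medians in place of quantile normalization, the authors' value table, no filter on dim probes, and a stricter filter at a detection p of 0.01. Others were a fit of only the arrays compared, eBayes with trend and robust settings, array weights, the replicate number as a block, and leaving out each array. The slide could not be used as a block because neither the labels nor the column headers name slides. No other batch is named, and no array was a copy of another.

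The procedure was tested on simulated data in 10 runs with 200 changed probes each, with the spread of the 8 arrays other than sea level replicate 3. In the runs with 9 arrays that array kept the size of its real deviations, with random signs. With all 9 arrays it recovered 36.8% of changes of 0.25, 68.6% of changes of 0.5, 84.8% of changes of 1 and 96.6% of changes of 2 on the log2 scale, with 31 false calls over all runs. Without sea level replicate 3 it recovered 63.6, 78.8, 93.0 and 99.0%, with 89 false calls. A list shifted by -0.3 was called in 10 of 10 runs both times, and 0 other lists were called. The shifted list was cholesterol synthesis, whose real median at 7 km was smaller, -0.16. Probes were simulated independently, so these runs cannot show how often camera calls unchanged lists whose genes move together. In the real data the correlation estimated for oxidative phosphorylation was 0.333. Python 3.11.15 with matplotlib 3.10.9 drew the plots.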

Results

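The series holds 9 expression arrays of rat brain cortex, 3 from rats at a simulated altitude of 7 km, 3 from rats at 3 km and 3 from rats at sea level. Each array gave a signal and a detection p-value for 22523 probes. On 8 of the arrays, 5881 to 6621 probes had a detection p-value below 0.05, the median signal was 121 to 159, and the Spearman correlation between arrays was 0.969 to 0.978. Sea level replicate 3 stood apart: its correlation with the other arrays was 0.642 to 0.660, its median signal was 204, and 8170 probes were detected. The series title names TFPI2, an inhibitor of tissue factor and plasmin, together with hypoxia of neurons, and the groups ask how the cortex transcriptome differs between altitudes. Because sea level replicate 3 enters every comparison with sea level, many results are also given without it (8 arrays, with 2 at sea level). This does not mean that the other 8 arrays are the sound ones, which was not settled.

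**Figure D1:**
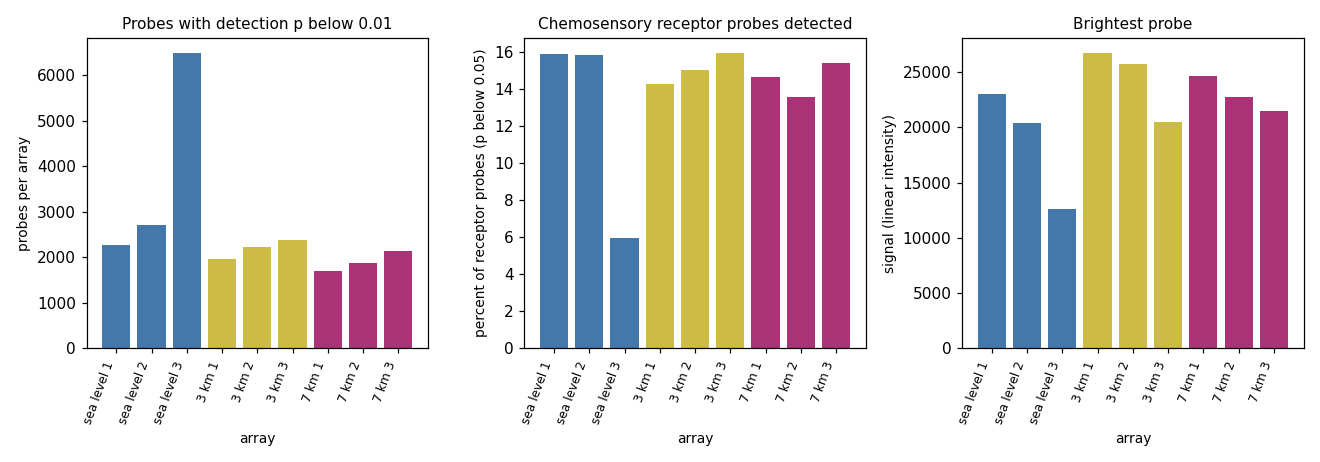
Bars give, for each of the 9 arrays, the number of probes with a detection p-value below 0.01, the percent of 1304 odorant, vomeronasal and taste receptor probes with a detection p-value below 0.05, and the signal of the brightest probe (linear intensity). Sea level replicate 3 has 6494 probes at the stricter threshold against 1710 to 2707 on the other arrays, 5.98% of receptor probes detected against 13.6% or more, and a brightest probe of 12571 against 20402 or more.

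Tfpi2 was not above background on any array: its probe had detection p-values of 0.159 to 0.612 over the 9 arrays, and no fold can be given. The probe of Slc2a1, the main glucose transporter of brain endothelium, was above background on 0 of 9 arrays. Epas1, which encodes HIF-2 alpha, and Hmox1, the inducible heme oxygenase, were each detected on 1 array, sea level replicate 3. Hif1a, which encodes the oxygen-regulated subunit of HIF-1, was detected on 8 of 9 arrays and did not pass at 7 km (log2 difference -0.08 ± 0.030 in the fit without the filter on dim probes). Vegfa, the main angiogenic growth factor, was also detected on 8 of 9 arrays and did not pass (0.04 ± 0.027 in the same fit). On 8 arrays their log2 differences in that fit were -0.04 ± 0.023 and 0.05 ± 0.015.

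At 7 km against sea level, transcripts of a secretory granule protein, of the squalene steps of cholesterol synthesis and of a few other proteins fell, and a secreted hormone rose. Scg3, a secretogranin of dense-core vesicles, fell by 0.50 ± 0.045 on the log2 scale (adjusted p = 0.0307), and Itm2a, a membrane protein of endothelium, fell by 0.50 ± 0.047 (adjusted p = 0.0307). Fdft1, squalene synthase, fell by 0.31 ± 0.036 and Sqle, squalene epoxidase, by 0.26 ± 0.030 (adjusted p = 0.0458 each). Enoph1, an enzyme of methionine salvage, fell by 0.62 ± 0.064 (adjusted p = 0.0328), and Luzp1, a leucine zipper protein, fell by 0.37 ± 0.036 (adjusted p = 0.0307). Stc1, the glycoprotein hormone stanniocalcin 1, rose by 0.44 ± 0.054 (adjusted p = 0.0494). Its probe was close to background at sea level, with detection p-values of 0.047, 0.034 and 0.062 on replicates 1, 2 and 3. The offset pulls the log2 difference of such a dim probe towards 0. In each of these genes all 3 arrays at 7 km lay on one side of all 3 at sea level. On 8 arrays the log2 differences were -0.50 ± 0.047 for Scg3, -0.39 ± 0.039 for Itm2a, -0.23 ± 0.027 for Fdft1, -0.17 ± 0.016 for Sqle, -0.50 ± 0.036 for Enoph1 and -0.33 ± 0.033 for Luzp1.

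**Figure D2:**
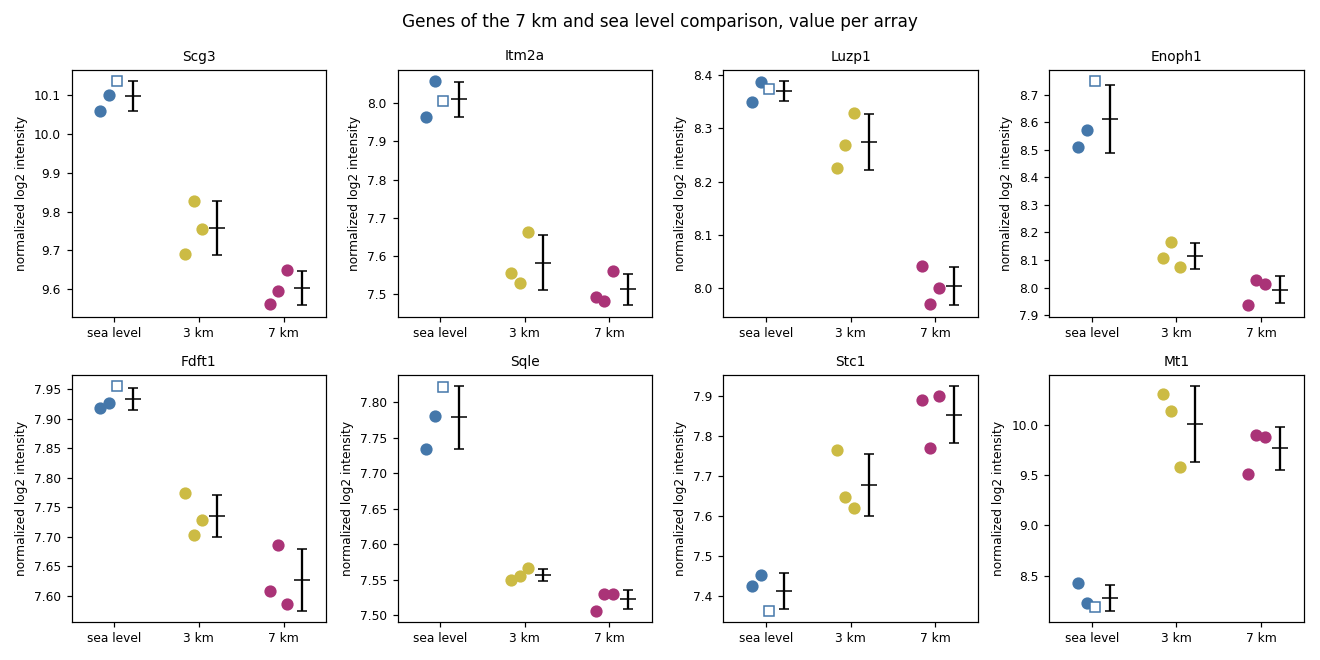
Points give the normalized log2 intensity of each array for the 7 named genes that passed at 7 km against sea level and for Mt1, which did not. Black bars are the mean and SD of 3 arrays, and the open square is sea level replicate 3. In Scg3, sea level averaged 10.10, 3 km 9.76 and 7 km 9.60, and in each of the 7 genes the mean at 3 km lies between the other group means. The 7 genes were chosen for their difference between 7 km and sea level, which favours that order. Between 7 km and 3 km 0 of 6656 probes passed.

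With all 9 arrays, 8 of 6656 probes passed, 1 higher and 7 lower, and 1 of the lower probes has no gene name. The balance of directions depends on the processing. Without background correction 11 passed, 5 higher and 6 lower. In the authors' value table, which differs in background and scaling, 5 passed, 4 higher and 1 lower, and without sea level replicate 3 that table gave 17 higher and 17 lower. The next named rises did not pass. These were Mt1, a metallothionein that binds zinc and copper (1.48 ± 0.19, adjusted p = 0.0507), Podxl, a sialoprotein of endothelium (0.42 ± 0.065, adjusted p = 0.0821), and Gjb6, connexin 30 of astrocyte gap junctions (1.16 ± 0.18, adjusted p = 0.0900). Tmem255b (0.23 ± 0.037, adjusted p = 0.0900) was another. Without sea level replicate 3, 20 of 6499 probes passed, 3 higher and 17 lower, and 7 of the 8 probes were shared; Stc1 did not pass there (0.31 ± 0.044). The larger set added falls of Omg, a glycoprotein of the myelin surface (0.88 ± 0.060), Ppp1r14a, an inhibitor of myosin phosphatase enriched in oligodendrocytes (0.85 ± 0.069), and Acat2, the cytosolic thiolase that starts sterol synthesis (0.75 ± 0.060). It also added falls of Ptp4a1, a phosphatase (0.52 ± 0.061), Lyzl4, a lysozyme-like protein (0.38 ± 0.044), Tubb3, the neuronal beta tubulin (0.33 ± 0.037), and Pdhx, a subunit of the pyruvate dehydrogenase complex (0.28 ± 0.033). Crip2, a LIM domain protein, rose by 0.74 ± 0.086 and Prr13 by 0.25 ± 0.027. Several of these values rest on leaving out that array. With all 9 arrays Prr13 had 1.87 ± 1.20, because it lay at 7.50 on sea level replicate 3 and at 12.39 and 12.37 on the other sea level arrays, and Tubb3 had -0.14 ± 0.17, with sea level replicate 3 at 7.80 below every 7 km array. Pdhx had -0.53 ± 0.18 and Ptp4a1 -0.79 ± 0.21 with all 9 arrays, and none of these genes passed there. Gpi, a glycolytic enzyme (0.77 ± 0.11), and Mif, a cytokine (0.40 ± 0.058), did not pass with those 8 arrays, and with all 9 they had 0.32 ± 0.31 and 0.61 ± 0.17. The count of 8 fell to 0 without 7 km replicate 1, 2 or 3, without 3 km replicate 1 or 2, and without sea level replicate 2, to 2 without 3 km replicate 3, and to 7 without sea level replicate 1. It was also 0 with median scaling, the stricter detection filter, only the 6 arrays compared and the replicate block, and 176 with array weights. Over 20 to 22 alternative settings, Itm2a passed in 11, Sqle in 10, Enoph1 in 9, Scg3 and Luzp1 in 6 each and Fdft1 and Stc1 in 5 each, with the sign unchanged in all of them.

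Cholesterol synthesis genes fell together at 7 km. Of 12 tested members, 11 were lower, with a median log2 difference of -0.16 (camera adjusted p = 2.65e-06; adjusted p = 0.0550 with an estimated correlation, and 3.55e-13 to 0.145 over its alternatives). Over all probes 2 members passed, and 7 fell when adjusted over the list alone. Beside Fdft1 and Sqle, these included Acat2 (-0.92 ± 0.12), Mvd, which makes isopentenyl diphosphate (-0.28 ± 0.050), and Nsdhl, a sterol dehydrogenase (-0.17 ± 0.032). On 8 arrays, 10 of 10 tested members were lower, with a median of -0.16 (adjusted p = 0.0341 with an estimated correlation) and 8 falls adjusted over the list alone. Many of these probes are dim, and the size of the median moved with the background handling, to -0.57 without background correction and -0.97 in the authors' value table.

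Oligodendrocyte genes also fell at 7 km. Of 16 tested markers, 15 were lower, with a median of -0.40 (camera adjusted p = 2.65e-06; adjusted p = 0.175 with an estimated correlation, and 3.19e-11 to 0.175 over its alternatives). None passed over all probes, and 8 fell when adjusted over the list alone. Examples were the myelin proteins Mog (-1.55 ± 0.23), Cnp (-1.16 ± 0.31) and Mal (-1.24 ± 0.25), and Ugt8, which makes galactocerebroside (-0.35 ± 0.056). The mean of the list against the 8-array mean was 0.25, 0.35 and 0.35 on the sea level arrays, -0.02 to 0.23 at 3 km, and -0.46, -0.08 and -0.33 at 7 km. On 8 arrays the median was -0.30, and 10 members fell adjusted over the list alone, with Ppp1r14a past the threshold over all probes. The median was -0.71 without background correction and -0.72 in the authors' value table. With an estimated correlation only 1 of 36 lists, cholesterol synthesis, passed at 7 km on 8 arrays. The oligodendrocyte, oxidative phosphorylation, TCA cycle and glycolysis lists did not.

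Genes of oxidative metabolism were lower and glycolytic genes higher at 7 km. Of 49 tested genes of oxidative phosphorylation, 43 were lower, with a median of -0.31 (camera adjusted p = 2.65e-06; adjusted p = 0.513 with an estimated correlation, and 2.95e-07 to 0.513 over its alternatives). None passed adjusted over the list alone; the complex I genes Ndufa11 (-0.49 ± 0.12) and Ndufs1 (-0.40 ± 0.11) and the ATP synthase gene Atp5f1d (-0.60 ± 0.15) had the smallest p-values. Sea level replicate 3 held the highest mean of this list, 0.56 against -0.18 to 0.11 on the other arrays, and without it the median was -0.15; it was -0.21 in the authors' value table. In the TCA cycle list 12 of 13 genes were lower, with a median of -0.16 (camera adjusted p = 0.00432; adjusted p = 0.513 with an estimated correlation, and 0.000423 to 0.513 over its alternatives). Pdhb, a subunit of pyruvate dehydrogenase, fell by 0.78 ± 0.17 adjusted over the list alone. The TCA cycle median was -0.11 on 8 arrays, -0.27 without background correction, -0.31 in the authors' value table and -0.37 with the stricter detection filter. Of 15 glycolytic genes, 13 were higher, with a median of 0.21 (camera adjusted p = 0.000614; adjusted p = 0.0705 with an estimated correlation, and 3.13e-05 to 0.944 over its alternatives). Adjusted over the list alone 3 rose: the phosphofructokinases Pfkl (0.26 ± 0.052) and Pfkp (0.21 ± 0.060) and the lactate transporter Slc16a3, which was not above background on any sea level array and was at least 1.07-fold higher. On 8 arrays the glycolysis median was 0.16, with 5 rises adjusted over the list alone, among them Gpi and Pfkl (0.16 ± 0.028 there).

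The other 3 lists that passed at 7 km were the proteasome, coagulation with fibrinolysis and matrix proteases, and angiogenesis. Of 26 proteasome genes, 24 were lower, with a median of -0.25 (camera adjusted p = 0.00316; adjusted p = 0.513 with an estimated correlation, and 0.000816 to 0.513 over its alternatives), and 0 passed adjusted over the list alone. Psmb5, a catalytic subunit, had a difference of -0.56 ± 0.16, and the median was -0.08 without sea level replicate 3 and -0.15 in the authors' value table. Of 15 genes of coagulation, fibrinolysis and matrix proteases, 12 were higher, with a median of 0.11 (camera adjusted p = 0.000684; adjusted p = 0.0705 with an estimated correlation, and 1.38e-05 to 0.145 over its alternatives). Adjusted over the list alone 3 rose: Serpine2, an inhibitor of thrombin and plasminogen activators (0.46 ± 0.10), Plat, tissue plasminogen activator (0.27 ± 0.070), and Anxa2, which binds it (0.17 ± 0.047). The median was 0.27 without background correction and 0.53 in the authors' value table. Leaving out sea level replicate 3 gave a median of 0.05, and 5 rose adjusted over the list alone, with Tfpi, a paralogue of Tfpi2 (0.19 ± 0.032), and Vwf, the von Willebrand factor (1.09 ± 0.32, and 1.79 ± 0.61 with all 9 arrays), among them. Of 8 angiogenesis genes, 7 were higher, with a median of 0.13 (camera adjusted p = 0.0238; adjusted p = 0.201 with an estimated correlation, and 1.15e-05 to 0.296 over its alternatives). Angpt2, a ligand of the endothelial receptor Tie2, rose adjusted over the list alone, was not above background on any sea level array and was at least 1.20-fold higher. The angiogenesis call ended without 7 km replicate 2, where the median was 0.11; it was 0.22 without sea level replicate 1 or 2, 0.08 without sea level replicate 3, 0.26 without background correction and 0.62 in the authors' value table.

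**Figure D3:**
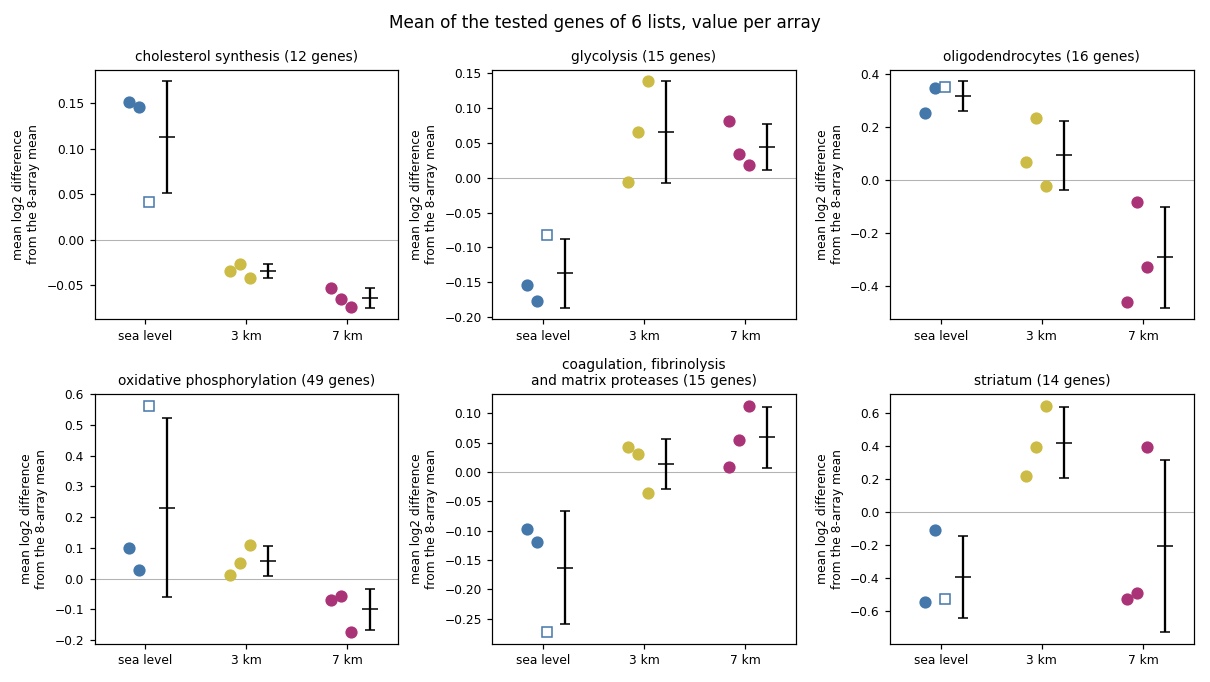
Points give, for each array, the mean over the tested genes of a list of the normalized log2 intensity, less the mean of the 8 arrays other than sea level replicate 3 (open square). Black bars are the mean and SD of the 3 arrays of a group. Cholesterol synthesis lies at 0.04 to 0.15 at sea level and at -0.07 to -0.03 at both altitudes, and in the striatum list 7 km replicate 3 lies at 0.40 beside -0.53 and -0.49 for the other two arrays at 7 km.

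Scaling to equal medians in place of quantile normalization moved the median of all tested probes to -0.64 at 7 km, -0.55 at 3 km and -0.06 for 7 km against 3 km, so list medians under it are read against those shifts. At 7 km oxidative phosphorylation (-1.32), proteasome (-1.30) and oligodendrocytes (-1.46) lay below the shift and passed. The TCA cycle (-1.22) also lay below it but no longer passed (adjusted p = 0.103, and 0.000423 to 0.513 over its alternatives). Cholesterol synthesis (-0.85) lay below it and coagulation with fibrinolysis and matrix proteases (-0.34) and angiogenesis (-0.30) above it without passing, while glycolysis (-0.75) lay below it, against its direction with quantile normalization. In the authors' value table the shift was 0.09 at 7 km and 0.12 at 3 km.

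The remaining 28 lists did not pass camera at 7 km. Fry also called 8 lists there, but not the same ones. Oxidative phosphorylation (fry adjusted p = 0.116), the TCA cycle (0.0743) and the proteasome (0.102) did not pass fry. The cell cycle (fry adjusted p = 0.0146), iron handling (0.0276) and apoptosis (0.0477) did. The values that follow are from camera. Among process lists, the medians and adjusted p-values were 0.07 and 0.146 for HIF targets, 0.04 and 0.133 for interferon response and antigen presentation, 0.06 and 0.216 for synaptic vesicle release, and 0.00 and 0.237 for apoptosis. They were 0.07 and 0.330 for autophagy and lysosome, 0.04 and 0.352 for the circadian clock, -0.02 and 0.421 for the cell cycle, and 0.02 and 0.449 for glutamate receptors and synapse. They were -0.03 and 0.638 for iron handling, -0.01 and 0.736 for immediate early genes, 0.01 and 0.748 for ion channels and pumps, and -0.03 and 0.770 for the unfolded protein response. Heat shock and chaperones had -0.03, glucocorticoid-responsive genes -0.07 and inflammation and cytokines -0.01, each with 0.832. Antioxidant and oxidative stress genes had -0.02 and ribosomal proteins -0.06, each with 0.944. Among cell and region markers, the values were 0.07 and 0.125 for microglia and macrophages, -0.07 and 0.216 for excitatory cortical neurons, -0.63 and 0.237 for choroid plexus and ependyma, -0.01 and 0.421 for astrocytes, and 0.06 and 0.421 for the striatum. They were -0.03 and 0.665 for oligodendrocyte precursors, -0.03 and 0.774 for interneurons, 0.04 and 0.984 for endothelium, and -0.02 and 0.944 for the thalamus. Pericytes and vascular smooth muscle had 0.00 and meninges and fibroblasts -0.02, each with 0.832. The choroid plexus median rests on sea level replicate 3, whose mean for that list was 1.54 against 0.22 and 0.29 on the other sea level arrays, and without it the median was -0.04. The choroid plexus gene Ttr, transthyretin, was above background on all 3 sea level arrays and on 0 arrays at either altitude; its SD over the sea level arrays was 2.44, and it was not tested without sea level replicate 3. Red cells and leukocytes had 4 tested members each, hippocampus 3 and hypothalamus and pituitary 1, too few for a test. Median and test differed in sign for 9 of these lists, among them astrocytes, heat shock, the thalamus and endothelium, and mean and test for 6.

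HIF targets and ribosomal proteins passed as well at 7 km on the 8 arrays without sea level replicate 3. Of 17 HIF targets 13 were higher, with a median of 0.05 (camera adjusted p = 0.0118; adjusted p = 0.214 with an estimated correlation, and 0.00135 to 0.975 over the alternatives). With all 9 arrays the HIF target median was 0.15 without background correction and 0.30 in the authors' value table, and in that table it was also 0.30 on 8 arrays, so its size rests on the background handling. Among the higher genes, P4ha1, a collagen prolyl hydroxylase (0.15 ± 0.042, and 0.08 ± 0.096 with all 9 arrays), and Bnip3l, a mitophagy receptor (0.49 ± 0.16, and 0.24 ± 0.21 with all 9), had the smallest p-values, and 0 members passed adjusted over the list alone. Tf, transferrin, a HIF target also made by oligodendrocytes, had -0.82 ± 0.19 there; with all 9 arrays it fell by 0.90 ± 0.16 adjusted over the list alone. Of 51 ribosomal protein genes 36 were higher, with a median of 0.05 (camera adjusted p = 0.0295; adjusted p = 0.499 with an estimated correlation, and 0.00139 to 0.994 over the alternatives), whereas the median with all 9 arrays was -0.06. In the authors' value table on 8 arrays the ribosomal median was 0.09.

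At 3 km against sea level, cholesterol synthesis genes fell and glycolytic and striatal genes rose as lists, while no probe passed alone. Of 12 cholesterol synthesis genes, 10 were lower, with a median of -0.14 (camera adjusted p = 8.42e-05; adjusted p = 0.0570 with an estimated correlation, and 4.53e-11 to 0.337 over its alternatives). Adjusted over the list alone 5 fell: Acat2 (-0.89 ± 0.12), Mvd (-0.24 ± 0.050), Sqle (-0.22 ± 0.030), Fdft1 (-0.20 ± 0.036) and Nsdhl (-0.17 ± 0.032). On 8 arrays these were -0.72 ± 0.060, -0.16 ± 0.037, -0.15 ± 0.016, -0.15 ± 0.027 and -0.13 ± 0.024. The cholesterol median was -0.14 on 8 arrays, -0.39 without background correction and -0.60 in the authors' value table. Of 15 glycolytic genes, 13 were higher, with a median of 0.28 (camera adjusted p = 0.000107; adjusted p = 0.0570 with an estimated correlation, and 1.11e-06 to 0.635 over its alternatives). Adjusted over the list alone 4 rose: Pfkp (0.34 ± 0.060), Tpi1, triosephosphate isomerase (0.30 ± 0.070), Pfkl (0.29 ± 0.052) and Gapdh (0.26 ± 0.077). The glycolysis median was 0.18 without sea level replicate 3 and 0.18 without background correction.

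All 14 tested striatum markers were higher at 3 km, with a median of 0.30 (camera adjusted p = 2.74e-05; adjusted p = 0.580 with an estimated correlation, and 1.57e-08 to 0.580 over its alternatives), and 0 passed adjusted over the list alone. The median was 0.82 without background correction, 1.36 in the authors' value table and 1.85 with the stricter detection filter. The largest single values were Rgs9, a regulator of G protein signalling of striatal neurons (2.65 ± 0.70), Ppp1r1b, the dopamine-regulated phosphoprotein DARPP-32 (1.98 ± 0.77, and 1.11 ± 0.53 without sea level replicate 3), and Adora2a, an adenosine receptor of striatal neurons (1.90 ± 0.63). The mean of the list was 0.22, 0.40 and 0.65 on the 3 km arrays and -0.54, -0.11 and -0.53 at sea level, and without 3 km replicate 3 the median was 0.16. The 3 km arrays that carried the lower cholesterol and higher glycolysis values are therefore also those with more striatal marker signal. At 7 km, however, replicates 1 and 2 had low striatum means of -0.53 and -0.49. Their cholesterol synthesis means were still low (-0.05 and -0.07), and their glycolysis means were 0.08 and 0.03, above every sea level array. The 7 km arrays cannot settle the question for the 3 km arrays. On 3 km replicates 1, 2 and 3 the glycolysis means were -0.01, 0.07 and 0.14, in the same order as the striatum means. The cholesterol synthesis means there were -0.03, -0.03 and -0.04. A striatal share in the glycolysis rise at 3 km stays open.

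Of 6656 probes 0 passed at 3 km with limma, and 537 had an unadjusted p below 0.05; without sea level replicate 3 it was 0 of 6499, with 616. The smallest adjusted p was 0.0782 with all arrays. The higher genes with the smallest p were Mt1 (1.72 ± 0.19), Wdr45, an autophagy protein (0.42 ± 0.056), Ccar2 (0.49 ± 0.067), Cryab, a small heat shock protein (0.75 ± 0.11), and Zfp593 (0.45 ± 0.073). The lower ones were Itm2a (-0.43 ± 0.047), Plekhg5 (-0.30 ± 0.037), Enoph1 (-0.50 ± 0.064), Scg3 (-0.34 ± 0.045) and Fez1, an adaptor of axonal transport (-0.42 ± 0.056). On 8 arrays the smallest adjusted p was 0.0530, for Omg (-0.72 ± 0.060), Acat2 (-0.72 ± 0.060) and Enoph1 (-0.40 ± 0.036) among the named genes. The count of 0 became 1 without 3 km replicate 3.

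The other 33 lists had medians from -0.80 to 0.10 at 3 km, the lowest being choroid plexus and ependyma, which had 0.0026 without sea level replicate 3, where the 28 lists that did not pass ranged from -0.07 to 0.09. With all 9 arrays the smallest adjusted p was 0.0613, shared by coagulation with fibrinolysis and matrix proteases, excitatory cortical neurons, oligodendrocytes, and microglia and macrophages. Median and test differed in sign for 5 of the 36 lists and mean and test for 3. Without sea level replicate 3, 8 lists passed. Beside the 3 above they were ribosomal proteins, with 46 of 51 genes higher (median 0.19, adjusted p = 0.248 with an estimated correlation, and 4.01e-10 to 0.921 over the alternatives), and oligodendrocytes (median -0.16 against -0.24 with all 9 arrays, adjusted p = 0.550 with an estimated correlation, and 0.00143 to 0.7003 over the alternatives). The ribosomal result is absent with all 9 arrays, where 27 of 51 genes were higher and the median was 0.0062 (camera adjusted p = 0.141). Angiogenesis had a median of 0.03 (adjusted p = 0.248 with an estimated correlation, and 0.000338 to 0.675 over the alternatives), and microglia and macrophages 0.05 (adjusted p = 0.263 with an estimated correlation, and 0.00822 to 0.817 over the alternatives). Coagulation with fibrinolysis and matrix proteases had 0.02 (adjusted p = 0.248 with an estimated correlation, and 0.00273 to 0.386 over the alternatives). With all 9 arrays the medians of these 3 lists were 0.10, 0.05 and 0.07. In the authors' value table on 8 arrays they were 0.36, 0.34 and 0.18, and that of oligodendrocytes was -0.29, so the sizes depend on the processing. That table differs in both background and scaling, and these values cannot part the 2. With all 9 arrays the oligodendrocyte median moved little, to -0.28 without background correction and -0.23 in the authors' value table. The cholesterol list had an adjusted p = 0.0475 with an estimated correlation on those 8 arrays, where it passed, and 0.0570 with all 9, where it did not.

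At 7 km against 3 km, oligodendrocyte, striatal, respiratory chain and proteasome genes were lower at the higher altitude as lists, and genes of glutamate receptors and synapse were slightly higher. With an estimated correlation 0 lists passed in this contrast. Of 16 oligodendrocyte genes 15 were lower, with a median of -0.15 (camera adjusted p = 1.14e-08; adjusted p = 0.156 with an estimated correlation, and 1.08e-18 to 0.156 over its alternatives), and 5 fell adjusted over the list alone, among them Mog (-1.01 ± 0.23) and Mal (-0.86 ± 0.25). The oligodendrocyte median was -0.25 without 7 km replicate 2, -0.31 without background correction, -0.48 in the authors' value table and -0.44 with the stricter detection filter. All 14 striatum genes were lower, with a median of -0.35 (camera adjusted p = 5.23e-08; adjusted p = 0.355 with an estimated correlation, and 2.08e-18 to 0.427 over its alternatives), as in Rgs9 (-2.14 ± 0.70). The striatum list was not lower on every 7 km array: its mean was -0.53 and -0.49 on 7 km replicates 1 and 2, but 0.40 on replicate 3, inside the range of 0.22 to 0.65 at 3 km. Without background correction the striatum median was -0.82, with the stricter detection filter -1.04, and in the authors' value table -1.24. Of 49 oxidative phosphorylation genes 45 were lower, with a median of -0.15 (camera adjusted p = 1.10e-07; adjusted p = 0.386 with an estimated correlation, and 4.61e-15 to 0.502 over its alternatives). Cox6a1, a subunit of cytochrome c oxidase, had -0.27 ± 0.080. Of 26 proteasome genes 21 were lower, with a median of -0.11 (camera adjusted p = 0.000365; adjusted p = 0.362 with an estimated correlation, and 3.89e-07 to 0.502 over its alternatives).

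The other lists that passed between the altitudes moved by less than 0.12 in values whose offset pulls dim probes towards 0. In the authors' value table cholesterol synthesis had -0.36, meninges and fibroblasts 0.31, iron handling -0.23, coagulation with fibrinolysis and matrix proteases 0.18, glutamate receptors and synapse 0.17 and synaptic vesicle release 0.13. Of 18 genes of glutamate receptors and synapse 17 were higher, with a median of 0.04 (camera adjusted p = 0.000622; adjusted p = 0.156 with an estimated correlation, and 0.000155 to 0.507 over its alternatives), as in Dlgap1, a scaffold of the postsynaptic density (0.20 ± 0.071). Of 16 genes of synaptic vesicle release 14 were higher, with a median of 0.07 (adjusted p = 0.435 with an estimated correlation, and 0.0145 to 0.955 over its alternatives). Its arrays did not separate: the mean of the list was 0.16, 0.03 and -0.12 at 7 km and -0.03, -0.09 and -0.06 at 3 km, so 7 km replicate 3 lay below every 3 km array. Of 51 ribosomal protein genes 40 were lower, with a median of -0.10 (adjusted p = 0.503 with an estimated correlation, and 7.82e-06 to 0.604 over its alternatives). Of 12 cholesterol synthesis genes 10 were lower, with a median of -0.04 (adjusted p = 0.227 with an estimated correlation, and 0.000373 to 0.984 over its alternatives). Of 15 genes of coagulation, fibrinolysis and matrix proteases 13 were higher, with a median of 0.04 (adjusted p = 0.227 with an estimated correlation, and 0.00282 to 0.507 over its alternatives). Of 14 genes of meninges and fibroblasts 12 were higher, with a median of 0.08 (adjusted p = 0.386 with an estimated correlation, and 9.71e-05 to 0.872 over its alternatives), though its list mean was -0.14, -0.05 and 0.29 at 7 km and -0.10, -0.10 and -0.05 at 3 km. Of 7 iron handling genes 6 were lower, with a median of -0.11 (adjusted p = 0.324 with an estimated correlation, and 0.000155 to 0.640 over its alternatives), and of 13 TCA cycle genes 9 were lower, with a median of -0.08 (adjusted p = 0.435 with an estimated correlation, and 0.00723 to 0.550 over its alternatives). Apart from oligodendrocytes, 0 members of these 12 lists passed adjusted over the list alone. Leaving out sea level replicate 3, which enters this contrast through the joint normalization and the spread, left 9 lists and moved the striatum median to -0.28.

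Several of the smaller differences between the altitudes rested on single arrays. The TCA cycle list no longer passed without 7 km replicate 2 (median -0.08) or 3 (-0.08), 3 km replicate 3 (-0.02), or sea level replicate 1 (-0.07) or 3 (-0.08). Synaptic vesicle release no longer passed without 7 km replicate 1 (0.03), 3 km replicate 1 (0.05) or 3 (0.07), or sea level replicate 3 (0.06). Coagulation with fibrinolysis and matrix proteases no longer passed without 7 km replicate 3 (0.04) or 3 km replicate 3 (0.02), ribosomal proteins without 7 km replicate 3 (-0.07) or 3 km replicate 3 (-0.07), and cholesterol synthesis without 7 km replicate 3 (-0.04) or 3 km replicate 1 (-0.04). Meninges and fibroblasts no longer passed without 7 km replicate 3 (0.01) or 3 km replicate 1 (0.07), and had 0.16 without 7 km replicate 1. Iron handling no longer passed without 7 km replicate 2 (-0.21) or 3 (-0.12), 3 km replicate 1 (-0.17), 2 (-0.09) or 3 (-0.23), or sea level replicate 1 (-0.11) or 3 (-0.11).

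With limma, 0 of 6656 probes passed between 7 km and 3 km, and 180 had an unadjusted p below 0.05; without sea level replicate 3 these numbers were 0 of 6499 and 532. The lower genes with the smallest p were Luzp1 (-0.27 ± 0.036, adjusted p = 0.718), Fis1, a mitochondrial fission protein (-0.30 ± 0.050), Cryab (-0.60 ± 0.11), Ccar2 (-0.36 ± 0.067) and Ndufs5, a complex I subunit (-0.55 ± 0.11). The higher ones were Nell2, a secreted neuronal protein (0.46 ± 0.11), Ubr4, a ubiquitin ligase (0.35 ± 0.081), Setd5 (0.19 ± 0.046), Cnksr2, a synaptic scaffold (0.49 ± 0.14), and Rnf145 (0.47 ± 0.14). The 24 lists that did not pass had medians from -0.10 to 0.04, with a smallest adjusted p of 0.0544; median and test differed in sign for 2 lists and mean and test for 4.

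The responses to both altitudes, each against the same sea level arrays, had a Pearson correlation of 0.908 across 6656 probes. Unchanged groups that share the same controls gave 0.917 in 200 simulations, with an SD of 0.0066, so the correlation itself does not exceed what the shared arrays produce. Without sea level replicate 3 it was 0.663 across 6499 probes, against 0.598 in simulations with an SD of 0.029. The covariance was 0.0751 against a simulated 0.0546 with all arrays and 0.0151 against 0.00738 without that array. No spread is given for the simulated covariances, so these gaps cannot be judged and do not show a shared response. Probes are not independent replicates, and with 3 controls the sea level arrays could not be divided into separate sets of 2 or more.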

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

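The tests of unspecific hybridisation, on 8 arrays and in the cholesterol probes tested without sea level replicate 3, and of a common weaker factor were chosen only after the result was seen; the other tests were written before. The 12 gene lists that differed between 7 km and 3 km came up because the direct contrast of the altitudes passed. Their median log2 differences were -0.147 for oligodendrocytes, -0.349 for striatum, -0.153 for oxidative phosphorylation, -0.113 for proteasome, -0.112 for iron handling, -0.0971 for ribosomal proteins, -0.0765 for TCA cycle and -0.0381 for cholesterol synthesis. Upward they were 0.0806 for meninges and fibroblasts, 0.0695 for synaptic vesicle release, 0.0422 for glutamate receptors and synapse, and 0.0354 for coagulation with fibrinolysis and matrix proteases. With a correlation estimated for each list 0 of the 12 passed camera.

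Splits of the 6 arrays of a contrast into 3 and 3 number 10, too few for a share under 0.05; every number of splits below includes the real one. At 7 km against sea level the real split gave 8 probes and the highest other 0, so only 1 split, the real one, gave as many. For lists it gave 8 and the highest other 7, again 1 split. At 3 km the real split gave 0 probes, as did all 10 splits, and 3 lists, with 5 in the highest other and 6 splits, the real one among them, giving at least as many. For 7 km against 3 km it gave 0 probes, as did all 10, and 12 lists, with 6 in the highest other, so that 1 split, the real one, gave as many.

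Sea level replicate 3 stood apart from the other 8 arrays. A tissue poor in excitatory neurons is argued against: the median percentile of excitatory neuron genes was 79.5 on it, 10.7 points above the lowest of the other arrays. The test cannot tell cortex from another tissue rich in these neurons, or from cortex with other tissue attached. This array had the highest list means for choroid plexus and ependyma (1.54) and for meninges and fibroblasts (0.44). The other arrays had at most 0.29 in either list. A common weaker factor is argued against too, since 73.2% of 183 bright probes lay within 4-fold of the median factor. Unspecific hybridisation on the other 8 arrays has the values it needs, as their share of detected receptor probes was at least 2.27 times that of this array, and it may explain the gap. The brightest receptor probe had a signal of 359 on this array and of 7011 or more on the others. If this explanation holds, every value given without sea level replicate 3 rests on the affected arrays alone. Leaving that array out would then be no check. A separate labelling or hybridisation day stays open because no batch is named, and no biological explanation was tested.

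Oligodendrocyte genes were lower at 7 km than at sea level. A single array at 7 km is argued against, since on the arrays without sea level replicate 3, leaving out 7 km replicate 1 as well kept 0.912 of the median. A lower share of oligodendrocytes in the dissected tissue cannot be told apart from lower expression in these cells: 93.8% of 16 markers were lower on 8 arrays, which either would give. An effect of altitude on these cells and an unnamed batch stay open too.

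Cholesterol synthesis genes were lower at both altitudes. With the oligodendrocyte score as a covariate the median at 3 km kept 0.915 of its size, which goes against a lower share of oligodendrocytes as the whole cause. The evidence is weak. The slope of the score rests on the spread within groups of only 8 arrays, and its uncertainty was not estimated. Of the 10 members tested without sea level replicate 3, 100% were above background on it, against the prediction for unspecific hybridisation in these probes. The test decides little, because that array detected 8170 probes, the most of any. Of 183 bright probes only 29 were not above background on it. Detection there also does not show that the signal on the other 8 arrays is specific. Unspecific hybridisation, an unnamed batch, differences between animals and altitude itself stay open.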

How the results depend on the processing

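The combinations that leave out sea level replicate 3 with another change were chosen only after the result was seen. Probes at 7 km against sea level (8) numbered 0 with median scaling, the stricter detection filter, only the 6 arrays compared and the replicate block, 5 in the authors' value table, 176 with array weights, and 0 to 20 leaving out 1 array. With sea level replicate 3 left out they were 73 with trend and robust settings and 34 in the authors' value table. Probes at 3 km (0) were 3 in the authors' value table, 1 with no filter, 3 with trend and robust settings, 120 with array weights and 0 to 1 leaving out 1 array. With sea level replicate 3 left out they were 42 with trend and robust settings, 7 among probes detected on it and 15 in the authors' value table. For 7 km against 3 km (0), the first and last of these gave 1 and 2. Lists at 7 km (8) were 3 with median scaling, 5 with the stricter filter and 0 with an estimated correlation. Fry gave 8 as well, but not the same lists. Lists at 3 km (3) were 5 with no background correction, 1 with median scaling, 6 in the authors' value table, 7 with no filter, 7 with only the 6 arrays, 6 with array weights, 0 with an estimated correlation and 3 to 8 leaving out 1 array. With sea level replicate 3 left out they were 10 with trend and robust settings, 6 among probes detected on it and 12 in the authors' value table. Lists for 7 km against 3 km (12) were 6 with the stricter filter, 0 with an estimated correlation, 2 with fry and 7 to 15 leaving out 1 array. The correlation of the responses (0.908) was 0.931 with no background correction, 0.946 with median scaling, 0.935 in the authors' value table, and 0.663 to 0.951 leaving out 1 array. Glycolysis at 7 km reversed to -0.755 with median scaling, where all probes shifted by -0.644, and ribosomal proteins (-0.057) to 0.106 with array weights, 0.0478 without sea level replicate 3 (also with trend and robust settings or probes detected on it) and 0.0893 with the authors' value table too. Leaving out 1 array gave ribosomal proteins -0.141 to 0.0478. The cause was not tested. Deviations of arrays with the same replicate number correlated at 0.0131 to 0.305, and those with different numbers at -0.303 to 0.277. Of the 9 pairs with the same number, 3 were over 0.1. Only 4 arrays had their highest correlation with their own number, so a pairing by number is not shown. For named genes 9733 values kept direction and side of the threshold, 132 passed newly, 98 no longer passed and 23 moved. Only 7 named genes passed with the main settings, so most of the 9733 are values that still did not pass. They say little about how stable the calls are. For lists 2349 values kept direction and side, 99 passed newly and 102 no longer passed, with 6 reversed. Tfpi2 was detected on 0 arrays. A slide block was not run because no slide is named. Dim signal limits the size of differences in probes near background.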

Other observations

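No test in this part was chosen after the result was seen; the values stand without explanation. Mt1, a metallothionein, had 1.48 ± 0.19 at 7 km and 1.72 ± 0.19 at 3 km on the log2 scale and passed at neither. The glucocorticoid-responsive gene Klf9 had -0.82 ± 0.15 at 7 km. Junb, an immediate early gene, had 1.27 ± 0.30 at 7 km, and C1qb, a complement gene of microglia, had 0.41 ± 0.085. None of the genes named here passed over all probes. Klf9 and Junb do not stand for their lists. Of the glucocorticoid-responsive genes, 2 rose and 3 fell adjusted over the list alone. Of the immediate early genes 0 passed that way, and 3 were higher and 3 lower at an unadjusted limma p below 0.05. Sea level replicate 3 had the lowest mean of the immediate early list, -0.32.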
